A study of Homo sapiens with 26 samples.

How the data were processed

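The analysis started from the read counts per gene that the authors deposited for 26 libraries. Upstream steps, per the submitters' processing notes, were base calling with CASAVA 1.8.2, alignment to hg19 with STAR 2.4.0h1 and counting with featureCounts 1.4.6. The notes do not state whether counting took the strand into account or which annotation was used, so a gene and an antisense partner, as in the HOX clusters, could not be told apart. Genes were identified by the symbols in the table. Of 42785 gene rows, 25317 names were matched to an Ensembl identifier of the supplied reference, which is on another genome build, so no coordinates were used. Counts of near-identical paralogs were taken as uncertain.

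The grouping by population and treatment, the comparisons, 30 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Replicate numbers follow the order of deposition and carry no other meaning. The title set was kept as a block, because pairs of libraries from different groups correlated in their deviations from the group means with a median of 0.147 (102 pairs) within a set and -0.072 (201 pairs) between sets. Replicate pairs had correlations of log2 CPM from 0.963 to 0.994.

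Counts were filtered with filterByExpr on the 10 groups, which left 20369 genes, and 8152 rows had no count in any library. Libraries were scaled by TMM. Negative binomial quasi-likelihood models were fitted in edgeR 4.0.16 under R 4.3.3, with a term for each group and the title set as block, 14 residual and 6 prior degrees of freedom and a common biological coefficient of variation of 0.235. Adjusted p-values are from edgeR by the method of Benjamini and Hochberg over all tested genes within a comparison, and genes under 0.05 were called. Standard errors of log2 changes were derived from the quasi-likelihood F statistic. Log2 CPM values used a prior count of 2. The mean treatment comparison averaged the SB/CHIR minus BVSAF difference over the 5 populations with equal weight, and population comparisons averaged both treatments. The interaction tested all differences between treatment responses together, and separate tests covered CD43+ minus mCherry+ CD34+ and mCherry- CD34+ minus mCherry+ CD34+ responses.

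Genes were named by rule in the mean treatment comparison, in mCherry+ CD34+ and CD43+ cells and in the population comparisons. The rule took the 10 largest positive and 10 largest negative log2 changes among called genes with a mean of at least 5 CPM in the higher arm and the same direction in every title set holding both arms, and 5 each way for the differences between responses. The rule thus fixed the agreement between title sets for the genes it named. Y-linked genes and XIST (1 gene), pseudogenes (303) and clone or accession names (4229) were left out of naming. Pseudogenes were recognised by symbol, so symbols absent from the reference were not screened. Every member of the 30 lists could also be named, and genes outside both were chosen after their values were seen. Some genes of the lists and of the rule are not reported here and were left out of the counts of gene results under alternatives, but they stayed in every fit and list test. A matched pair is a pair of libraries of the compared groups from the same title set. Agreement of sign between matched pairs is no independent support for a called gene, because the same libraries made the call. Where a group had no read of a gene, the change is given as at least a fold against a floor of 3 counts per library, from 0.156 to 0.292 CPM as group means after TMM scaling. Floors and such bounds cover counting error only.

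Lists with at least 4 tested members were tested with camera in limma 3.58.1 on voom values with the same design and a preset correlation of 0.01, adjusted over 30 lists. Camera was repeated with an estimated correlation and without the block, and fry was run beside it. Of 165 list calls over all comparisons 16 held with an estimated correlation. Because voom weights make that estimate depend on the order of the design columns, it was repeated with the columns reversed, where 24 held, 15 of them in both orders. These 15 were the HOXA and HOXD lists for the treatment in mCherry+ CD34+ cells, endoderm in mCherry+ CD34- cells, cardiac in marker-negative cells, HOXB and arterial for the differences between responses, arterial for CD43+ cells, and pan-endothelial, arterial and mesenchymal for mCherry+ CD34- and marker-negative cells, with hematopoietic transcription factors and epithelial for the former.

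The alternatives tried were DESeq2 1.42.0, limma voom, RLE scaling, no filter, a filter of 5 CPM in 2 libraries, no block, fits on the compared groups alone, each title set left out, each title set alone with additive terms, and each library left out. A further alternative, without the BVSAF mCherry+ CD34+ and marker-negative libraries of EN_30_d11P, was chosen after the data were seen. Where a group was left with 1 library, that library was assumed to vary like those of the other groups. The fit on the compared groups alone was not run for the mean treatment and the interaction, which use all groups. EN_30_d11P alone lacks mCherry+ CD34- cells.

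The steps were tested on simulated data drawn with the fitted means and dispersions, with changes planted in known genes. Only genes above a minimum mean count were changed, so recovery of genes near the floor was not measured. Libraries were drawn without an effect shared by populations of a culture, so false calls from such an effect were not measured either. For the mean treatment (19852 genes) edgeR recovered 70.1% of genes changed 1.5-fold, 86.6% at 2-fold and 97.0% at 4-fold, with 2.9% false calls, against 12.5% for DESeq2 and 2.3% for limma voom. Within populations recovery at 2-fold was 40.3% in mCherry+ CD34+, 49.3% in mCherry- CD34+, 28.4% in mCherry+ CD34-, 52.2% in CD43+ and 62.7% in marker-negative cells. For the interaction 20.9% were recovered at 2-fold and 65.2% at 4-fold. Camera called the planted list (adjusted p = 1.8e-102) and 0 random lists, of 30 lists in all, and fry called 2 of the random lists. Genes were simulated as independent, so these list results could not show how camera behaves with correlated genes.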

Results

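RNA was sequenced from cells that had been differentiated from the human H9 embryonic stem cell line and then sorted. The line carried mCherry in the SOX17 locus and GFP in RUNX1C. Day 10 and day 11 cultures had grown in BMP4, VEGF, SCF, activin A and FGF (BVSAF), or in the same factors after SB431542 and CHIR99021 were added at day 2 (SB/CHIR). SB431542 blocks ALK4, ALK5 and ALK7, receptors of the activin, NODAL and TGF-beta signals, and CHIR99021 blocks GSK3 and so raises WNT signalling. Cells were separated by mCherry, CD34 and CD43 into 5 populations: mCherry+ CD34+ CD43- (6 libraries), mCherry- CD34+ CD43- (5 libraries), mCherry+ CD34- CD43- (4 libraries), mCherry- CD43+ (5 libraries) and cells without any of the markers (6 libraries). These populations are called mCherry+ CD34+, mCherry- CD34+, mCherry+ CD34-, CD43+ and marker-negative below. The 26 libraries made 10 groups of 2 or 3, with 13 libraries per treatment. Sample titles placed the libraries in 3 sets: EN_30_d11P (day 11, 7 libraries), EN_39_d10 (day 10, 9 libraries) and EN_39_d10P (day 10, 10 libraries). Depth ran from 5.99 to 20.9 M counts per library, with a median of 17.6 M. The lowest depth belonged to the BVSAF marker-negative library of EN_30_d11P, and the next lowest was 11.0 M. Every p-value below measured only the spread between these libraries, because the labels do not say whether replicates were separate cultures. The labels also do not say whether the populations of a title set and treatment were sorted from the same culture. If they were, the mean treatment p-values and the counts of matched pairs took fractions of a culture as replicates of the treatment.

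The transcripts of the sorted proteins mostly followed the gates. SOX17 stood at 28.9 ± 7.48 CPM (mean ± SD, 3 libraries) in BVSAF mCherry+ CD34+ cells and at 60.9 ± 21.5 CPM (3 libraries) with SB/CHIR. In mCherry- CD34+ cells SOX17 stood at 4.03 ± 0.246 CPM (2 BVSAF libraries) and 5.55 ± 1.78 CPM (3 SB/CHIR libraries). The mCherry+ CD34- cells held 12.8 ± 5.43 CPM with BVSAF but 7.33 ± 2.22 CPM with SB/CHIR, which overlapped the mCherry- CD34+ range. CD34 reached 807 ± 178 CPM in BVSAF mCherry+ CD34+ cells and 2.34 CPM in BVSAF marker-negative cells. SPN, which encodes CD43, reached 723 ± 142 CPM in BVSAF CD43+ cells (3 libraries). The mCherry- CD34+ cells, sorted as CD43-, still held 67 ± 5.07 CPM of SPN with BVSAF. SPN was also at 39.6 and 37.7 CPM in the BVSAF mCherry+ CD34+ and marker-negative libraries of EN_30_d11P. RUNX1, the transcription factor needed for blood to form from endothelium, stood at 432 ± 37.4 CPM in BVSAF CD43+ cells and 44.6 ± 14.5 CPM in BVSAF mCherry+ CD34+ cells. The first component of the expression values held 49% of the variance and the second 24.7%.

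**Figure D1:**
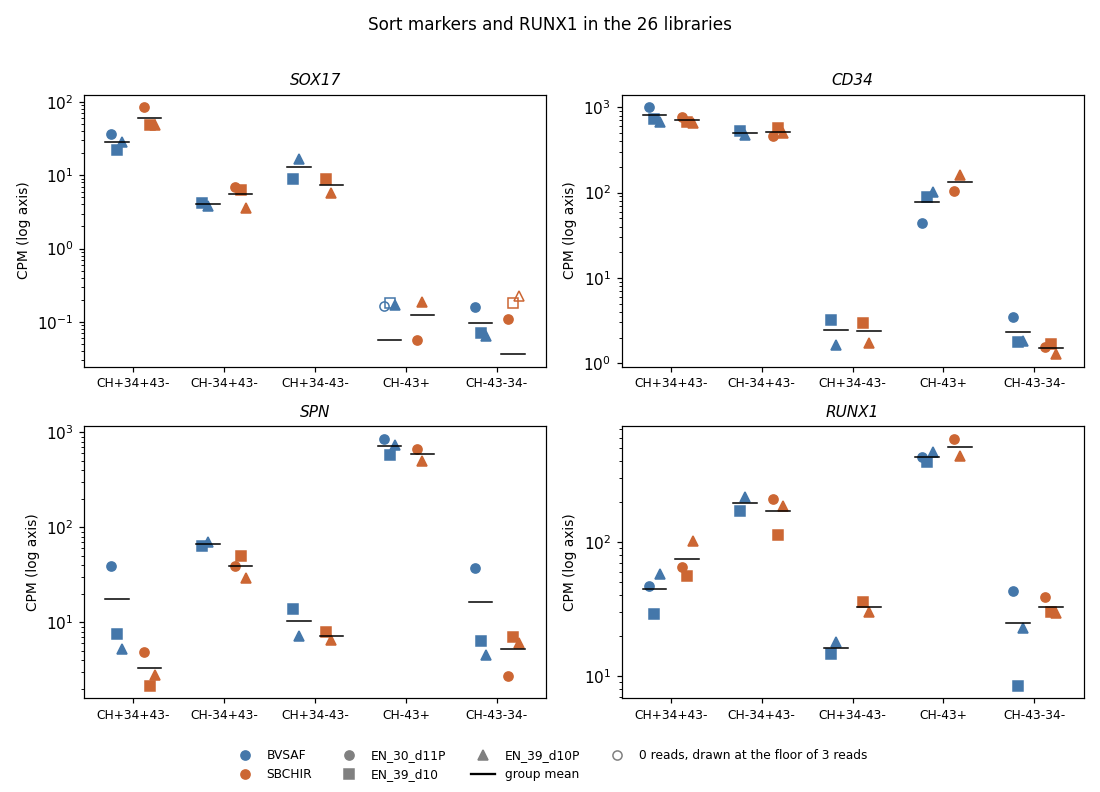
Expression in CPM of SOX17, CD34, SPN and RUNX1 on log axes, with 1 point per library (blue BVSAF, orange SB/CHIR), marker shape for the title set and a black line for the group mean. Each sorted protein's transcript was highest in a population gated for it, and open points are libraries without a read, drawn at the floor of 3 reads.

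The first question was what SB/CHIR changed on average over the 5 populations. By list, HOXA, HOXC and HOXD genes rose and erythroid, megakaryocyte and cardiac genes fell, but these list calls were lost with an estimated correlation. HOXA9, a posterior HOX gene needed by blood stem cells, rose at least 7.19-fold (adjusted p = 3.1e-10) from a floor, since BVSAF CD43+ cells held no read of it. HOXB9 rose by 2.87 ± 0.16 on the log2 scale (± standard error, adjusted p = 3.2e-10). HOXA9 and HOXB9 were higher in all 12 matched pairs of libraries, which came from only 3 title sets. HOXC10, which marks lumbar levels of the trunk, rose at least 11.5-fold (adjusted p = 9.3e-06). In the same way HOXA5 rose at least 8.29-fold (adjusted p = 0.00012) and HOXA10 at least 3.55-fold (adjusted p = 1.7e-07). HOXC6 rose by 2.51 ± 0.22 (adjusted p = 2.3e-07). CDX4, an activator of posterior HOX genes, rose at least 5.29-fold (adjusted p = 4e-05). HOXB4, used to expand blood progenitors in culture, fell by 0.58 ± 0.08 on the log2 scale (adjusted p = 3.1e-05, 11 of 12 pairs). HOXB1, an anterior HOX gene of the hindbrain and early heart, fell by 1.36 ± 0.26 on the log2 scale, or by 2.22 without SB/CHIR CD43+ replicate 1.

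Outside the HOX clusters, CXCL12, the niche chemokine read by CXCR4, rose by 2.06 ± 0.19 (adjusted p = 3.6e-07). PRRX1, a limb and trunk mesenchyme regulator, rose by 2.21 ± 0.20 (adjusted p = 2.3e-07). ALDH1A2, which makes retinoic acid, rose by 1.69 ± 0.15 (adjusted p = 2.4e-07). The axonal kinesin gene KIF1A rose from 5.99 to 73.2 CPM (log2 change 3.27 ± 0.16, adjusted p = 1e-10). HSPA6, an inducible heat shock gene, rose by 3.93 ± 0.49 (adjusted p = 1.4e-05, 11 of 12 pairs). FBXL21, whose symbol had no match in the reference, so that it was not screened as a pseudogene, rose by 2.85 ± 0.44 (adjusted p = 0.00014). The stem cell transcript ESRG rose by 2.90 ± 0.32 (adjusted p = 2.9e-06, 9 of 12 pairs). PRPH, a peripheral neuron filament, rose at least 2.89-fold (adjusted p = 4.7e-06). AXIN2, a direct WNT target, rose by 0.86 ± 0.12 (adjusted p = 7.2e-05, 10 of 12 pairs). The pluripotency factor SOX2 rose by 3.30 ± 0.42 (adjusted p = 1.6e-05, 11 of 12 pairs) and the epithelial junction gene CLDN4 by 1.50 ± 0.15 (adjusted p = 7.2e-07, 11 of 12 pairs).

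Among the genes that fell, NKX2-3, a homeobox gene of gut and spleen vessels, lost 4.16 ± 0.56 on the log2 scale (adjusted p = 3.4e-05, 11 of 12 pairs). The integrin ligand NPNT fell from 109 to 9.80 CPM (log2 change -3.40 ± 0.37, adjusted p = 3.4e-06). AFP, the main secreted protein of fetal liver and yolk sac endoderm, fell by 4.77 ± 0.92 on the log2 scale (adjusted p = 0.0011, 11 of 12 pairs). The epicardial regulator TBX18 fell by 2.54 ± 0.24 on the log2 scale (adjusted p = 5.4e-07). MEIS2, a HOX cofactor, fell by 0.70 ± 0.07 on the log2 scale (adjusted p = 1e-06, 11 of 12 pairs). PROM1, a progenitor surface gene, fell by 1.73 ± 0.16 on the log2 scale (adjusted p = 4.7e-07, 11 of 12 pairs). The matrix genes DCN and POSTN fell by 1.33 ± 0.16 (adjusted p = 9.4e-06) and 1.45 ± 0.17 (adjusted p = 9.3e-06) on the log2 scale. EGR1, an immediate early gene, fell by 0.87 ± 0.08 on the log2 scale (adjusted p = 4.7e-07, 11 of 12 pairs). The fibrinogen gene FGA fell at least 3.42-fold, a call lost without BVSAF mCherry- CD34+ replicate 1 (log2 change -3.50). AHSP, the alpha hemoglobin chaperone, fell by 3.32 ± 0.73 on the log2 scale, a call lost without BVSAF mCherry+ CD34- replicate 1 (-3.08), and without EN_39_d10 the calls of FGA and AHSP were lost.

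By fixed list, 10 of 11 HOXA genes, 5 of 7 HOXC genes and 4 of 8 HOXD genes rose and none fell. Adjusted over the list alone, the counts were 10, 5 and 5. Camera called the HOXA list (adjusted p = 1.9e-11), the HOXC list (adjusted p = 1.3e-08) and the HOXD list (adjusted p = 7.2e-08), but with an estimated correlation the adjusted p was 0.11 for each. With genes that had a group at 0 held to the floor, the median log2 changes of these lists were 1.53, 2.15 and 1.38, against fitted medians of 2.57, 2.51 and 2.24. In the HOXB list 3 of 10 genes rose and 3 fell (adjusted over the list alone 4 and 3, camera adjusted p = 0.92). Erythroid genes fell in 12 of 16 cases and 4 were not called (adjusted over the list alone 15 fell), with a median log2 change of -2.39. Camera called the erythroid list (adjusted p = 1.5e-07), lost with an estimated correlation (adjusted p = 0.37). SPN, the CD43 gene, fell as well, by 1.05 ± 0.27 on the log2 scale (adjusted p = 0.0087). None of the 16 erythroid genes was called in CD43+ cells themselves. The erythroid median was -4.95 in mCherry+ CD34+, -1.05 in mCherry- CD34+, -1.64 in mCherry+ CD34-, -1.15 in CD43+ and -3.16 in marker-negative cells. Among megakaryocyte genes 6 of 10 fell in the mean over populations (9 over the list alone), and that list's camera adjusted p of 3.3e-05 also became 0.37. Of the 11 cardiac genes 7 fell and 1 rose (camera adjusted p = 0.015, or 0.35 with an estimated correlation). Of the 17 mesenchymal and smooth muscle genes 8 fell and 3 rose (camera adjusted p = 0.0029, or 0.37). WNT target genes rose in 5 of 11 cases (camera adjusted p = 0.035, or 0.37), pluripotency genes in 4 of 7 (0.0036, or 0.35) and epithelial genes in 4 of 8 (0.0012, or 0.35). The 14 proliferation genes held no call (camera adjusted p = 0.63), and 3 of 17 pan-endothelial genes rose and 2 fell (camera adjusted p = 0.57).

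In total 4201 of 20369 genes were called, 2457 higher and 1744 lower with SB/CHIR, of which 750 and 334 were at least 2-fold. That count was 804 without EN_39_d10, 1343 without EN_39_d10P, 740 in EN_39_d10 alone and 746 in EN_39_d10P alone. In EN_30_d11P alone edgeR called 0 genes, with 1504 at an unadjusted p under 0.05, while limma voom called 8 and DESeq2 called 277.

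**Figure D2:**
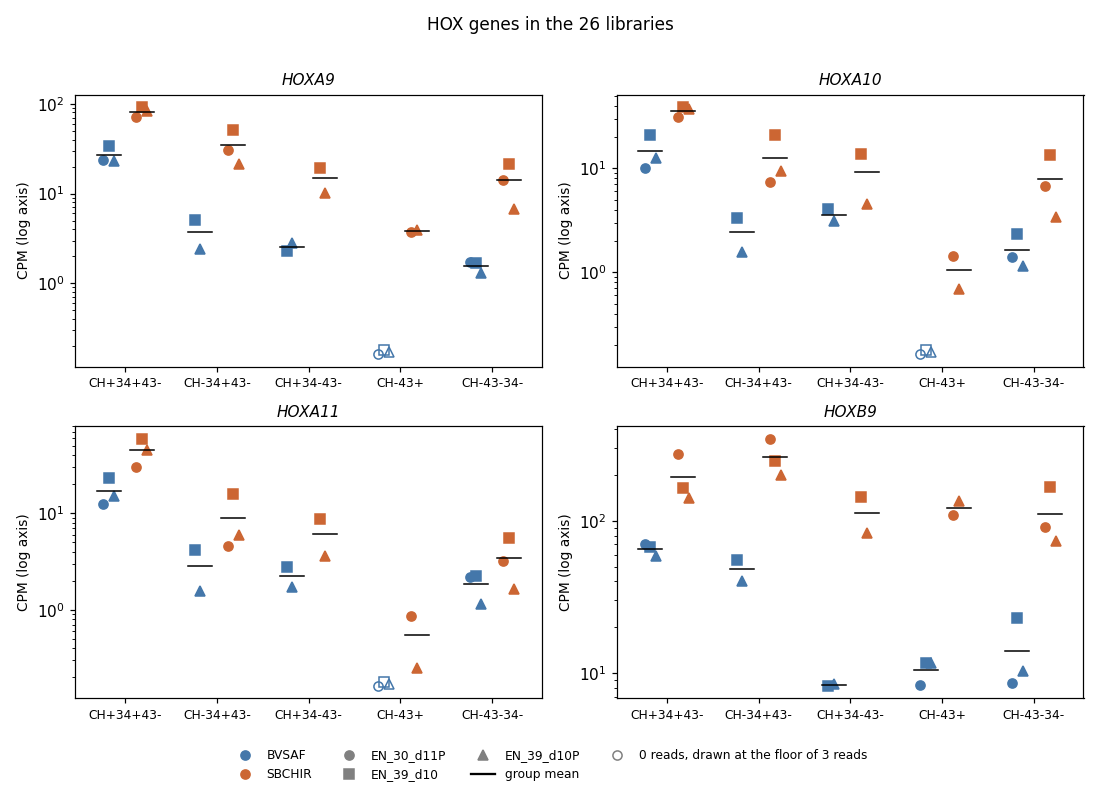
Expression in CPM of HOXA9, HOXA10, HOXA11 and HOXB9 on log axes in the 5 populations, with 1 point per library (blue BVSAF, orange SB/CHIR), marker shape for the title set and a black line for the group mean. HOXA transcripts were highest in mCherry+ CD34+ cells and had no read in BVSAF CD43+ cells, where open points lie at the floor of 3 reads.

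The next question was what SB/CHIR changed within the mCherry+ CD34+ cells, the arterial-like population of 3 libraries per treatment. The HOXA and HOXD lists rose, while falls of the erythroid, endoderm and mesenchymal lists were called only with the preset correlation. HOXA5 rose from 1.09 ± 0.571 to 15.4 ± 4.18 CPM (log2 change 3.93 ± 0.58, adjusted p = 0.00063). HOXA3 rose from 0.461 ± 0.138 to 5.20 ± 1.77 CPM (3.44 ± 0.47, adjusted p = 0.00034). HOXA9 was present with BVSAF at 26.9 ± 6.43 CPM and rose to 81.9 CPM (1.64 ± 0.24, adjusted p = 0.00067). HOXB9 rose from 65.7 ± 6.28 to 194 ± 71.8 CPM (1.56 ± 0.30, adjusted p = 0.0036). HOXB4 fell by 0.89 ± 0.16 on the log2 scale (adjusted p = 0.0021). AGTR2, an angiotensin II receptor, rose from 1.59 ± 0.786 to 23.1 ± 7.62 CPM (3.79 ± 0.52, adjusted p = 0.00035). ADCYAP1R1, the receptor of the peptide PACAP, rose from 3.45 ± 1.42 to 28.8 ± 5.42 CPM (3.09 ± 0.30, adjusted p = 6.8e-06). PRND, the endothelial prion-like protein doppel, rose from 13.6 ± 5.07 to 95.4 ± 17.6 CPM (2.83 ± 0.30, adjusted p = 3e-05). SELE, the adhesion receptor E-selectin, rose from 9.02 ± 5.92 to 49.4 ± 27.9 CPM (2.53 ± 0.34, adjusted p = 0.00029). The potassium channel KCNJ2 rose by 2.77 ± 0.41 (adjusted p = 4e-04), the retinoid- and estrogen-metabolising enzyme CYP1B1 by 2.88 ± 0.44 (adjusted p = 0.00057), the pentraxin NPTX2 by 2.65 ± 0.33 (adjusted p = 8.9e-05) and the guanylate cyclase subunit GUCY1A2 by 2.65 ± 0.47 (adjusted p = 0.0021). AXIN2 rose to 22.5 ± 5.02 CPM (1.20 ± 0.21, adjusted p = 0.0022). Every called list member in this population moved the same way in all 3 title sets, a condition that the naming rule had set for those it also named.

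Fetal growth factor IGF2 rose from 4990 ± 1480 to 13100 ± 690 CPM in these cells (log2 change 1.42 ± 0.30, adjusted p = 0.0075). Its call was lost without BVSAF mCherry+ CD34+ replicate 2 (1.19). STAB2, a scavenger receptor of sinusoidal endothelium, fell from 94.0 ± 70.7 to 18.4 ± 15.8 CPM (-2.40 ± 0.31, adjusted p = 0.00014). MEIS2 fell from 157 ± 31.7 to 45.6 ± 6.07 CPM (-1.78 ± 0.15, adjusted p = 1.1e-06). The synapse organiser CBLN2 fell from 6.21 ± 2.39 to 0.138 CPM (-5.43 ± 0.55, adjusted p = 1.1e-05). AFP fell from 39.8 ± 33.5 to 0.121 CPM (-8.30 ± 1.46, adjusted p = 0.002), and the fibrinogen gene FGB fell by 7.44 ± 1.29 on the log2 scale (adjusted p = 0.0018). The matrix gene POSTN fell by 2.41 ± 0.36 (adjusted p = 0.00053) and the cardiac and endodermal factor GATA4 by 2.21 ± 0.43 (adjusted p = 0.0041) on the log2 scale. Embryonic globin HBE1 fell from 169 ± 203 to 1.65 ± 0.783 CPM (-6.22 ± 1.47, adjusted p = 0.018), a call lost without SB/CHIR replicate 1 (-6.20), SB/CHIR replicate 2 (-5.54) or BVSAF replicate 1 (-4.26). The thyroid hormone carrier TTR fell by 5.63 on the log2 scale, a call lost without SB/CHIR replicate 2 (-5.26). SPN, the CD43 gene, fell with the blood genes by 2.17 ± 0.60 on the log2 scale (adjusted p = 0.044). SOX17 rose by 1.05 ± 0.29 (adjusted p = 0.041), and RUNX1 changed by 0.76 ± 0.29 without being called (adjusted p = 0.19).

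Within mCherry+ CD34+ cells 8 of 11 HOXA genes rose (adjusted over the list alone 11), with a median log2 change of 2.14. Camera called the HOXA list (adjusted p = 4.1e-18) and the HOXD list (adjusted p = 1.5e-10, 5 of 8 genes higher), and both stayed called with an estimated correlation (adjusted p = 0.031 for each). The HOXC list had 4 of 7 genes higher (camera adjusted p = 3.7e-07, or 0.13 with an estimated correlation). Of the 16 erythroid genes 10 fell (14 over the list alone), with a median of -4.95 (camera adjusted p = 1.4e-08, or 0.24 with an estimated correlation). Endoderm genes fell in 7 of 11 cases (camera adjusted p = 2.8e-05, or 0.13) and mesenchymal genes in 7 of 17 (3.5e-05, or 0.22). WNT targets rose in 3 of 11 cases (0.0086, or 0.24). The arterial and Notch list held 1 higher and 1 lower of 19 genes (camera adjusted p = 0.20), and none of the 17 pan-endothelial genes was called (camera adjusted p = 0.55). In all, 375 genes rose and 446 fell, 821 together.

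Leaving out libraries or sets lowered that count of 821 to 523 (BVSAF replicate 1), 482 (BVSAF replicate 2), 375 (SB/CHIR replicate 2), 459 (SB/CHIR replicate 3), 464 (no block for title set), 99 (without EN_39_d10) and 207 (without EN_39_d10P). Without EN_39_d10 the calls of HOXB4, CYP1B1, GUCY1A2, AXIN2, IGF2, POSTN and HBE1 were lost, without EN_39_d10P those of HOXB9, HOXB4, IGF2, GATA4 and HBE1, and without the block those of SELE and AXIN2.

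In the mCherry- CD34+ cells (3 SB/CHIR and 2 BVSAF libraries) the question was whether the other endothelial population changed alike, and there arterial genes fell. GJA5, the gap junction protein of arteries, fell from 270 ± 64.2 to 37.9 ± 14.3 CPM (log2 change -2.83 ± 0.44, adjusted p = 7e-04). CXCR4, the receptor of CXCL12 found on arterial tips, fell from 121 ± 5.38 to 21.7 ± 14.5 CPM (-2.53 ± 0.39, adjusted p = 0.00069). DLL4, the arterial Notch ligand, fell from 223 ± 5.97 to 77.8 ± 28.2 CPM (-1.64 ± 0.31, adjusted p = 0.0039). EFNB2, the classic artery marker ephrin B2, fell from 1050 ± 37.2 to 430 ± 145 CPM (-1.29 ± 0.21, adjusted p = 0.00087). MECOM, a stem cell and arterial transcription factor, fell from 283 ± 15.9 to 101 ± 23.8 CPM (-1.46 ± 0.23, adjusted p = 0.00091). STAB2 fell from 155 ± 87.5 to 27.1 ± 9.00 CPM (-2.88 ± 0.34, adjusted p = 4.4e-05) and PROM1 from 24.8 ± 3.41 to 3.82 ± 1.68 CPM (-2.68 ± 0.32, adjusted p = 4.4e-05). IGF2 fell from 3420 ± 671 to 807 ± 370 CPM (-2.03 ± 0.33, adjusted p = 0.00093). HOXA9 rose from 3.74 ± 1.88 to 34.5 ± 15.3 CPM (3.26 ± 0.32, adjusted p = 1.6e-05) and HOXB9 from 47.8 to 264 ± 75.8 CPM (2.47 ± 0.36, adjusted p = 0.00044). ALDH1A2 rose from 21.2 ± 11.3 to 84.6 ± 56.5 CPM (2.03 ± 0.29, adjusted p = 0.00034). Of the 19 arterial and Notch genes 7 fell and 1 rose (adjusted over the list alone 9 and 2), with a median log2 change of -0.74. Camera called that list (adjusted p = 1.7e-07) and the call held with an estimated correlation (adjusted p = 0.023), though not with the design columns in reverse order (adjusted p = 0.052). HOXA genes rose in 7 of 11 cases (camera adjusted p = 7.1e-12, or 0.083 with an estimated correlation), and the 14 proliferation genes held no call over all genes but 11 over the list alone (camera adjusted p = 2e-06, or 0.27). Pan-endothelial genes (median -0.30, camera adjusted p = 2.7e-05, or 0.27) and pan-hematopoietic genes (median -0.69, 0.0055, or 0.31) were called lower and epithelial genes higher (median 1.19, 4.6e-05, or 0.19). A change in the mix of cells within this sort was not tested. Every called list member in this population had the same sign in both matched pairs, which the calls from these same libraries made likely.

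In these mCherry- CD34+ cells 955 genes were called, 498 higher and 457 lower. The count was 175 without BVSAF replicate 1, 247 without BVSAF replicate 2, 561 without SB/CHIR replicate 2, 620 without SB/CHIR replicate 3, 439 without the block, 59 without EN_39_d10, 64 without EN_39_d10P, 1653 without EN_30_d11P and 1852 from this population's own libraries. The calls of DLL4 (log2 change -1.39) and EFNB2 (-0.99) were lost without BVSAF replicate 1. DLL4, EFNB2, MECOM, IGF2 and ALDH1A2 lost theirs without EN_39_d10, GJA5, CXCR4, DLL4 and HOXB9 without EN_39_d10P, and ALDH1A2 without the block.

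**Figure D3:**
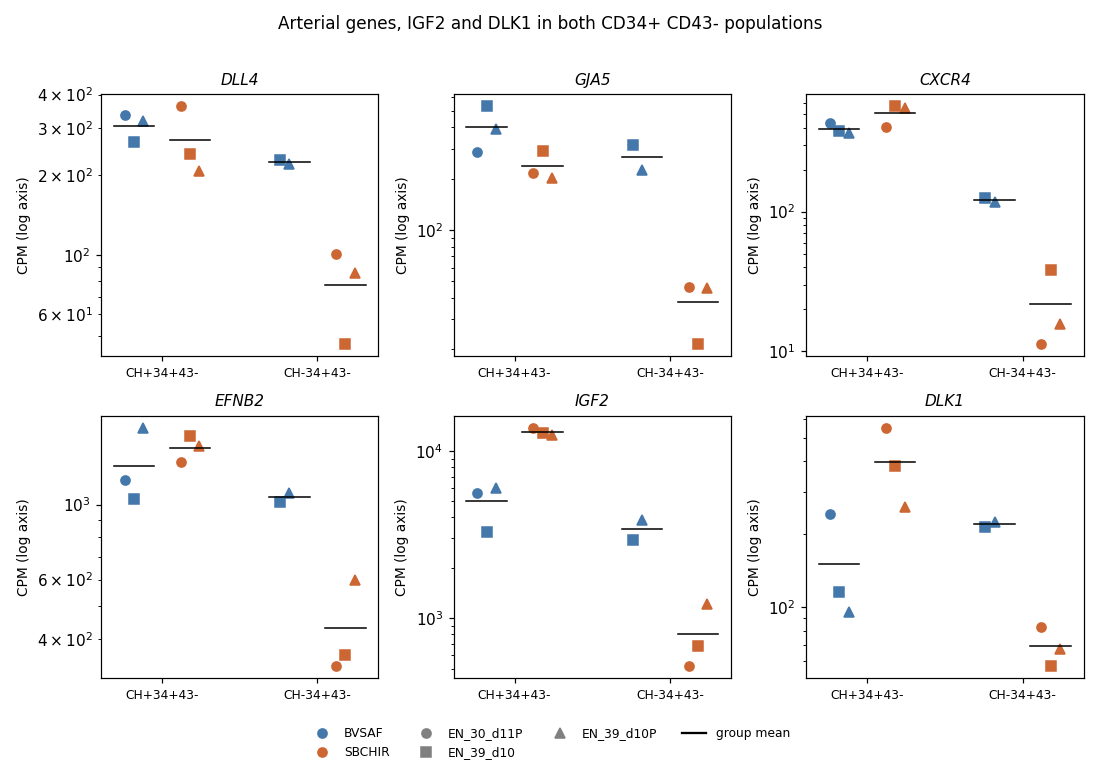
Expression in CPM of DLL4, GJA5, CXCR4, EFNB2, IGF2 and DLK1 on log axes in the CD34+ CD43- populations, with 1 point per library (blue BVSAF, orange SB/CHIR), marker shape for the title set and a black line for the group mean. In mCherry- CD34+ cells the SB/CHIR points lie under the BVSAF points for each of these genes.

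In the mCherry+ CD34- cells (2 libraries per treatment), where the question was which cells besides endothelium carried the SOX17 reporter, SB/CHIR lowered endoderm genes. HNF4A, a master regulator of liver and visceral endoderm, fell from 44.4 ± 10.0 to 2.35 ± 0.698 CPM (log2 change -4.20 ± 0.41, adjusted p = 1.9e-05). AFP fell from 1260 ± 602 to 25.8 ± 35.3 CPM (-5.63 ± 1.18, adjusted p = 0.0086), but its call was lost without BVSAF replicate 1 (-4.96) or SB/CHIR replicate 1 (-4.23), and the change was -10.74 without SB/CHIR replicate 2 and -10.92 without EN_39_d10P. HOXB9 rose from 8.36 ± 0.204 to 113 ± 42.9 CPM (3.70 ± 0.41, adjusted p = 7.2e-05) and HOXA9 from 2.55 ± 0.346 to 14.7 ± 6.40 CPM (2.45 ± 0.34, adjusted p = 0.00055). Endoderm genes fell in 8 of 11 cases and none rose (adjusted over the list alone 9 fell), with a median log2 change of -3.43. Camera called the endoderm list (adjusted p = 5.3e-16) and the call held with an estimated correlation (adjusted p = 0.0052). HOXC genes rose in 4 of 7 cases (7 over the list alone, camera adjusted p = 8.3e-10, or 0.061 with an estimated correlation). All 42 called list members had the same sign in both matched pairs, which the calls from these same libraries made likely. Here 296 genes rose and 481 fell, 777 together. That count was 89 without BVSAF replicate 1, 428 without BVSAF replicate 2, 99 without SB/CHIR replicate 1, 356 without SB/CHIR replicate 2, 378 without the block, 101 without EN_39_d10P and 1488 without EN_30_d11P. Without EN_39_d10 edgeR and limma voom called 0 genes, with 1292 at an unadjusted p under 0.05 in edgeR and 63 called by DESeq2, and the genes named here lost their calls.

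In CD43+ cells (2 SB/CHIR and 3 BVSAF libraries) the question was whether blood cells made with SB/CHIR kept the HOX code, and several HOXA and HOXB genes rose there. HOXA9 stood at 3.82 ± 0.173 CPM with SB/CHIR and had no read in any BVSAF library, a rise of at least 21.3-fold (adjusted p = 4.3e-06). HOXA10 stood at 1.05 ± 0.519 CPM against no read, at least 5.89-fold higher (adjusted p = 0.00029). HOXB9 rose to 122 ± 18.1 CPM (log2 change 3.65 ± 0.34, adjusted p = 8e-06) and HOXB8, a block on myeloid maturation, from 1.10 ± 0.379 to 8.27 ± 0.514 CPM (2.90 ± 0.33, adjusted p = 2.8e-05). PROK1, an endothelial mitogen, rose from 0.294 ± 0.299 CPM by 5.31 ± 0.71 on the log2 scale (adjusted p = 0.00017). TECRL, an enzyme gene linked to heart rhythm, rose from 1.03 ± 0.237 to 15.0 ± 1.56 CPM (3.74 ± 0.53, adjusted p = 0.00027). HMGA2, a fetal growth regulator of blood stem cells, rose from 34.7 ± 9.65 to 131 ± 36.1 CPM (1.92 ± 0.28, adjusted p = 0.00039). FLT1, a VEGF receptor, rose from 6.70 ± 3.06 to 42.0 ± 4.84 CPM (2.62 ± 0.29, adjusted p = 2.2e-05) and the endothelial matrix gene MMRN2 from 9.30 ± 3.22 to 32.3 ± 3.80 CPM (1.87 ± 0.25, adjusted p = 0.00015). With SB/CHIR these were 2.14% and 2.53% (FLT1) and 4.28% and 4.14% (MMRN2) of the mCherry+ CD34+ level, while endothelial EMCN was at 0.31% and 0.287%. Carry-over of CD34+ cells was not tested for rises of endothelial or arterial genes. LGALSL, a galectin-like gene, fell from 98.7 to 27.2 CPM (-1.84 ± 0.30, adjusted p = 0.001), a call lost without SB/CHIR replicate 1 (-1.46). The platelet tubulin TUBA8 fell by 2.44 ± 0.58 on the log2 scale (adjusted p = 0.018), a call lost without BVSAF replicate 1 (-1.75) or SB/CHIR replicate 1 (-1.63). The pericyte regulator RGS5 rose by 3.62 ± 0.51 (adjusted p = 0.00029) and by 1.73 without SB/CHIR replicate 1.

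The calls of several other genes depended on single CD43+ libraries. Calprotectin subunits S100A8 and S100A9 rose by 2.96 ± 0.60 (adjusted p = 0.006) and 2.41 ± 0.50 (adjusted p = 0.0073). Their calls were lost without BVSAF CD43+ replicate 1 (2.53 and 2.00) and without SB/CHIR CD43+ replicate 1 (1.36 and 1.17). The chitinase-like gene CHI3L1 rose by 3.71 and the carboxylesterase CES1 by 3.77, calls lost without SB/CHIR CD43+ replicate 1 (0.20 and 0.97). The neutrophil defensin DEFA3, whose near-identical paralogs leave its counts uncertain, rose by 4.05, also lost without that library (2.19). DEFA4, another defensin, rose by 3.51 ± 0.65 (adjusted p = 0.0057), by 3.34 in EN_30_d11P and 3.02 in EN_39_d10P, a call lost without SB/CHIR CD43+ replicate 1 (2.69) or BVSAF CD43+ replicate 1 (5.39). HBE1 stood at 2210 ± 1970 CPM with SB/CHIR and 6420 ± 793 CPM with BVSAF, without a call (-0.70 ± 1.21, adjusted p = 0.86).

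As lists, HOXB genes rose in 5 of 10 cases in CD43+ cells (6 over the list alone), with a median log2 change of 1.14. Camera called the HOXB list (adjusted p = 4.8e-06), a call lost with an estimated correlation (adjusted p = 0.051), though not with the design columns in reverse order (adjusted p = 0.049). HOXA genes rose in 4 of 11 cases (camera adjusted p = 1.2e-06, or 0.23 with an estimated correlation), with a fitted median of 4.14 that was 1.4 with genes without a read held to the floor. Arterial and Notch genes rose in 7 of 19 cases (camera adjusted p = 4.5e-05, or 0.074) and pan-endothelial genes in 5 of 17 (0.011, or 0.48). Of the fetal RNA-binding and growth genes 1 of 8 rose, without a list call (0.71). None of 16 erythroid genes was called, though camera called the list lower (adjusted p = 2.5e-14, median -1.15), a call lost with an estimated correlation (adjusted p = 0.19). Megakaryocyte genes had 1 lower of 10 (camera adjusted p = 3.8e-14, or 0.074), and with reversed columns the arterial and megakaryocyte lists were at 0.049 too. Proliferation genes had none of 14 called (median -0.42, camera adjusted p = 3.9e-07, or 0.27). Of 907 called genes 820 rose and 87 fell, so that 90.4% were higher. The count was 297 without BVSAF replicate 1, 153 without SB/CHIR replicate 1, 539 without the block, 98 without EN_30_d11P, 252 without EN_39_d10, 437 without EN_39_d10P and 546 from these libraries alone. Without EN_30_d11P the calls of HOXA10, TECRL, RGS5 and TUBA8 were lost, and without EN_39_d10 that of TUBA8, with CHI3L1 and CES1 lost in either case.

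The marker-negative cells (3 libraries per treatment) answered what SB/CHIR did to the remaining culture, where pluripotency genes rose and mesenchymal and cardiac genes fell, and of these lists only the cardiac one stayed called with an estimated correlation. SOX2 rose from 0.117 ± 0.103 to 7.77 ± 3.10 CPM (log2 change 5.86 ± 0.60, adjusted p = 4.4e-06). TDGF1, the NODAL coreceptor CRIPTO, rose from 0.708 ± 0.370 to 21.3 ± 9.89 CPM (4.83 ± 0.52, adjusted p = 7.3e-06). COL1A2, a fibrillar collagen, fell from 5660 ± 1290 to 1940 ± 494 CPM (-1.56 ± 0.24, adjusted p = 0.00024). DCN fell from 386 ± 71.7 to 76.9 ± 19.1 CPM (-2.34 ± 0.31, adjusted p = 5.3e-05) and POSTN from 573 ± 33.3 to 132 ± 17.9 CPM (-2.13 ± 0.33, adjusted p = 0.00024). TBX5, a regulator of heart and forelimb, fell from 6.08 ± 3.45 to 0.344 CPM (-4.07 ± 0.53, adjusted p = 5e-05) and TBX18 from 19.7 to 2.06 CPM (-3.30 ± 0.47, adjusted p = 0.00012). IGF2 fell from 8380 ± 1710 to 1790 ± 936 CPM (-2.33 ± 0.31, adjusted p = 5.6e-05) and the imprinted gene DLK1 from 804 ± 245 to 127 ± 38.5 CPM (-2.66 ± 0.38, adjusted p = 0.00011). HOXA9 rose from 1.57 ± 0.240 to 14.1 ± 7.37 CPM (3.14 ± 0.31, adjusted p = 6.8e-06) and HOXB9 from 13.9 ± 7.85 to 110 ± 49.0 CPM (2.95 ± 0.32, adjusted p = 8.1e-06). CXCL12 rose from 42.4 to 240 CPM (2.34 ± 0.33, adjusted p = 1e-04), ALDH1A2 from 3.04 to 17.9 CPM (2.65 ± 0.29, adjusted p = 9.4e-06), and PROM1 fell from 103 ± 27.8 CPM by 2.91 ± 0.28 on the log2 scale (adjusted p = 2.2e-06). HOXB1 fell by 2.45 ± 0.33 on the log2 scale (adjusted p = 7.2e-05). Mesenchymal genes fell in 11 of 17 cases with 1 higher (camera adjusted p = 4.5e-07, or 0.14 with an estimated correlation). Cardiac genes fell in 7 of 11 cases (camera adjusted p = 7e-07, kept at 0.039 with an estimated correlation) and pluripotency genes rose in 6 of 7 (7e-07, or 0.081). HOXB genes fell in 4 of 10 cases with 1 higher (0.024, or 0.25). In total 1224 genes rose and 1302 fell, 2526 together. That count was 1515 without SB/CHIR replicate 1, 1197 without BVSAF replicate 2, 1425 without SB/CHIR replicate 2, 1581 without the block, 342 without EN_39_d10 and 814 without EN_39_d10P. Of 101 called list members 100 had the same sign in all 3 matched pairs, which the calls from these same libraries made likely.

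**Figure D4:**
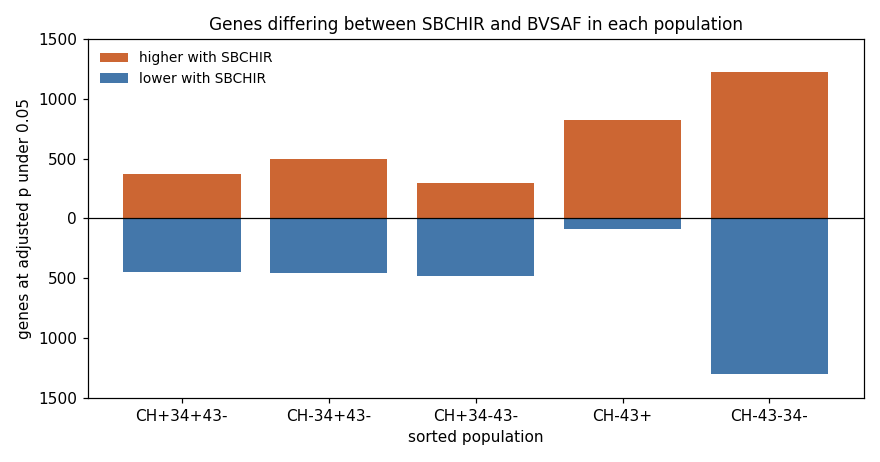
Number of genes called higher (up) and lower (down) with SB/CHIR in each population, edgeR adjusted p under 0.05. Most called genes of the CD43+ cells lie on the higher side, and the marker-negative cells hold the largest total.

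Whether the treatment acted differently between populations was tested directly. The treatment by population interaction was called for 1396 of 20369 genes, with 3964 at an unadjusted p under 0.05. IGF2 was among them (adjusted p = 0.00015), with a rise of 1.42 in mCherry+ CD34+ cells and falls of 2.03 in mCherry- CD34+ and 2.33 in marker-negative cells on the log2 scale. DLK1 (adjusted p = 0.00078), CXCR4 (adjusted p = 0.00056), GJA5 (adjusted p = 0.0022), EFNB2 (adjusted p = 0.0061), UNC5B (adjusted p = 0.0011), MECOM (adjusted p = 0.0052), HNF4A (adjusted p = 4.6e-05), TDGF1 (adjusted p = 0.00032) and HOXA9 (adjusted p = 0.00084) were called too. The interaction count was 694 without the block, 2423 with DESeq2, 899 without SB/CHIR CD43+ replicate 1, 18 without EN_39_d10 and 198 without EN_39_d10P.

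Between the CD34+ populations, the treatment response of mCherry- cells minus that of mCherry+ cells was called for 72 genes, 15 higher and 57 lower. IGF2 differed by -3.45 ± 0.44 (adjusted p = 0.00044) and PRND by -6.38 ± 0.69 (adjusted p = 9.7e-05). The butyrophilin-like gene BTNL9 differed by -4.41 ± 0.49 (adjusted p = 9.7e-05) and the bicarbonate transporter SLC4A4 by -3.45 ± 0.36 (adjusted p = 6.6e-05). The arterial genes CXCR4 (-2.87 ± 0.52, adjusted p = 0.014), EFNB2 (-1.51 ± 0.28, adjusted p = 0.015) and UNC5B (-1.56 ± 0.30, adjusted p = 0.022) were called, while GJA5 (-2.04, adjusted p = 0.16) and DLL4 (-1.45, adjusted p = 0.17) were not. The calls of CXCR4, EFNB2 and UNC5B were lost without BVSAF mCherry+ CD34+ replicate 2 (-2.65, -1.48 and -1.34), and each was also lost without a BVSAF mCherry- CD34+ library. RYR3, a calcium release channel, differed by 2.59 ± 0.34 (adjusted p = 0.00044). Camera called the arterial and Notch list for this difference, and the call held with an estimated correlation (adjusted p = 0.0038). The count of 72 was 17 without BVSAF mCherry- CD34+ replicate 1, 16 without its replicate 2, 29 without BVSAF mCherry+ CD34+ replicate 2, 38 without SB/CHIR mCherry+ CD34+ replicate 2, 18 without the block, 209 with DESeq2, 209 without a filter, 117 with limma voom, 192 without EN_30_d11P, 3 without EN_39_d10 and 11 without EN_39_d10P.

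For CD43+ cells minus mCherry+ CD34+ cells, 484 genes were called, 455 higher and 29 lower. HOXA9 differed at least 7.00-fold (adjusted p = 0.00039), HOXB8 by 3.18 ± 0.40 (adjusted p = 0.00027) and HOXB9 by 2.09 ± 0.44 (adjusted p = 0.014). SEMA3C, a guidance ligand of vessels and heart outflow, differed by -2.57 ± 0.43 (adjusted p = 0.0024) and DLK1 by -2.58 ± 0.56 (adjusted p = 0.016). HOXB9 lost its call without BVSAF CD43+ replicate 1 (1.92) or SB/CHIR CD43+ replicate 2 (1.72), and DLK1 without SB/CHIR CD43+ replicate 1 (-1.96). The HOXB list kept its camera call with an estimated correlation (adjusted p = 0.038). The count of 484 was 202 without BVSAF CD43+ replicate 1, 106 without SB/CHIR CD43+ replicate 1, 268 and 316 without SB/CHIR mCherry+ CD34+ replicates 2 and 3, 242 without the block, 815 with DESeq2, 774 without a filter, 304 with limma voom, 120 without EN_30_d11P, 64 without EN_39_d10, 84 without EN_39_d10P and 137 from these libraries alone.

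Called genes were shared between most populations. Between mCherry+ CD34+ and mCherry- CD34+ cells 130 genes rose in both, against 9.17 for independent lists. Of the genes lower in mCherry+ CD34+, mCherry- CD34+ and mCherry+ CD34- cells, 10, 9 and 2 were also lower in CD43+ cells. Independent lists would share 1.9, 1.95 and 2.05. Of the same genes 29, 35 and 17 were higher in CD43+ cells, where 820 calls were higher and only 87 lower. The number of such opposite calls for independent lists was not computed. Over all populations 17 genes were higher in each of the 5 and 0 were lower in each of the 5. Those 17 included PRRX1, HOXA9, HOXC6, HOXB9, KIF1A, the kinesin KIF5C, the vesicle linker MLPH, the vitamin D enzyme CYP27B1 and the chemokine CX3CL1. Another 223 genes were higher in some populations and lower in others.

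**Figure D5:**
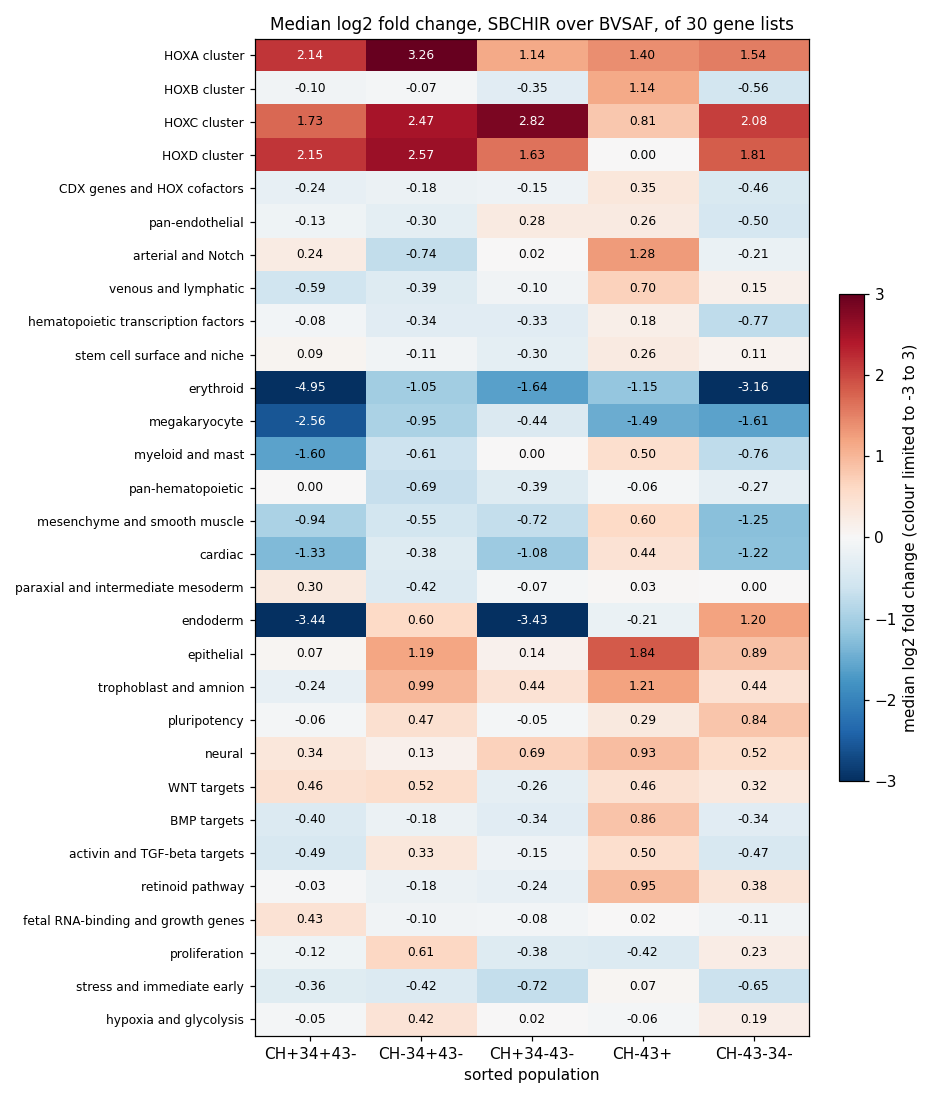
Median log2 change with SB/CHIR of the genes of each of 30 fixed lists (rows) in the 5 populations (columns), with genes that had a group without reads set at the floor and colours limited to -3 to 3. The HOXA, HOXC and HOXD lists are on the higher side in most populations, and the erythroid, megakaryocyte and endoderm lists are low in mCherry+ CD34+ cells.

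The remaining questions concerned the populations, tested with both treatments weighted alike. By list, arterial and HOXA genes were higher in mCherry+ CD34+ cells (6 libraries) than in mCherry- CD34+ cells (5 libraries) and mesenchymal genes lower, calls lost with an estimated correlation. PRND was higher by 6.40 ± 0.34 (adjusted p = 1.8e-09), at 54.5 against 0.773 CPM. CXCR4 was higher by 3.24 ± 0.29 (adjusted p = 2.2e-07) and the tight junction gene CLDN5 by 2.25 ± 0.19 (adjusted p = 9.5e-08). GJA4, a connexin of arteries, was higher by 1.78 ± 0.31 (adjusted p = 0.00024), GJA5 by 1.58 ± 0.30 (adjusted p = 0.00049), DLL4 by 1.10 ± 0.21 (adjusted p = 0.00062) and EFNB2 by 1.08 ± 0.14 (adjusted p = 1.4e-05). These averages joined unlike treatments. GJA5 stood at 405 against 270 CPM with BVSAF and at 237 against 37.9 CPM with SB/CHIR. EFNB2 stood at 1300 against 1050 CPM with BVSAF and at 1470 against 430 CPM with SB/CHIR. As ratios, the gaps of DLL4, CXCR4, IGF2 and PRND were also wider with SB/CHIR, and those of HOXA9 and HOXA10 were narrower. HLF, a stem cell transcription factor, was higher by 3.18 ± 0.28 (adjusted p = 1.7e-07) and MECOM by 1.21 ± 0.16 (adjusted p = 1.8e-05). IGF2 was higher by 2.38 ± 0.24 (adjusted p = 7.7e-07), HOXA9 by 2.14 ± 0.20 (adjusted p = 6.2e-07) and HOXA10 by 2.21 ± 0.24. AGTR2 (5.65 ± 0.58, adjusted p = 1.6e-06), the fucosyltransferase FUT9 (4.98 ± 0.68, adjusted p = 3.6e-05), the metalloreductase STEAP2 (4.15 ± 0.26, adjusted p = 3.5e-09), the endothelial carbonic anhydrase CA4 (4.10 ± 0.40), FCGR2B (3.86 ± 0.33) and BTNL9 (3.77 ± 0.27) were also higher.

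Lower in mCherry+ CD34+ than in mCherry- CD34+ cells were some blood factors, among them GFI1B (-3.75 ± 0.58, adjusted p = 7.5e-05), GFI1 (-2.99 ± 0.33), IKZF1 (-2.70 ± 0.20, adjusted p = 3.5e-08) and SPI1 (-2.59 ± 0.42). RUNX1 was lower by 1.72 ± 0.22 on the log2 scale (adjusted p = 9.2e-06) and SPN by 3.16 ± 0.43 (adjusted p = 2.1e-05), so that these factors moved with the CD43 transcript. The muscarinic receptor CHRM2 (-3.43 ± 0.25), the platelet regulator RGS18 (-3.43 ± 0.55), the matrix protein gene RELN (-3.23 ± 0.43), the progenitor factor ZBTB16 (-3.06 ± 0.35), the macrophage receptor CSF1R (-2.50 ± 0.30) and COL1A1 (-2.67 ± 0.28, adjusted p = 1.2e-06) were lower. Arterial and Notch genes were higher in 11 of 19 cases and lower in 2 (12 and 2 over the list alone), with a median of 0.89 (camera adjusted p = 2.8e-06, or 0.065 with an estimated correlation). Mesenchymal genes were lower in 13 of 17 cases (1.4e-09, or 0.077) and pan-endothelial genes higher in 9 of 17 (2.7e-06, or 0.30). HOXA genes were higher in 6 of 11 cases (2.9e-05, or 0.35), and proliferation genes lower in 9 of 14 (0.00023, or 0.44). Among the blood lists, hematopoietic transcription factors (0.43), pan-hematopoietic (0.11) and erythroid genes (0.42) were not called, and megakaryocyte (0.038, or 0.55) and myeloid genes (0.018, or 0.44) lost their calls with an estimated correlation. In total 2701 genes were higher and 3129 lower, 5830 together. The count was 3592 without BVSAF mCherry- CD34+ replicate 2, 1508 without EN_39_d10, 1492 without EN_39_d10P, 1378 in EN_39_d10 alone and 1067 in EN_39_d10P alone. In EN_30_d11P alone edgeR and limma voom called 0 genes, with 1702 at an unadjusted p under 0.05 in edgeR and 299 called by DESeq2.

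CD43+ cells (5 libraries) against mCherry+ CD34+ cells (6 libraries) showed what separated blood from the arterial-like cells. Embryonic globin HBE1 was higher by 8.70 ± 1.10 (adjusted p = 6.5e-07), at 4310 against 85.3 CPM, and HBZ by 8.31 ± 0.96. The HBE1 value averaged unlike ratios, 6420 against 169 CPM with BVSAF and 2210 against 1.65 CPM with SB/CHIR. Carried-over CD43+ cells may add to the BVSAF level in mCherry+ CD34+ cells. KLF1, the erythroid master regulator, was higher by 7.75 ± 0.57 (adjusted p = 2.2e-10), at 119 against 1.98 CPM. AHSP was higher by 7.99 ± 0.81. GFI1B (6.69 ± 0.59), the myeloid factor SPI1 (5.81 ± 0.44, adjusted p = 3e-10), the neutrophil enzyme MPO (7.28 ± 0.75), the platelet chemokine PF4 (6.49 ± 0.78), PTPRC, which encodes CD45 (4.95 ± 0.56), MYB (2.65 ± 0.27) and RUNX1 (2.96 ± 0.23, adjusted p = 3.8e-10) were higher too. The cell cycle genes MKI67 (1.86 ± 0.18, adjusted p = 1.8e-08) and TYMS (1.89 ± 0.13) rose with them. Endothelial CLDN5 was lower by 9.62 ± 0.32 on the log2 scale (adjusted p = 2e-15), the cadherin CDH5 by 5.51 ± 0.30 (adjusted p = 2.2e-12) and DLL4 by 7.98 ± 0.32. The somatostatin receptor SSTR1 (-9.47 ± 0.27, adjusted p = 5e-16), the vascular proteoglycan ESM1 (-9.61 ± 0.65) and PRND (-9.79 ± 0.45) were lower. As means of both treatments, HOXA9, HOXA10 and HOXA11 were at least 56.8-fold, 52.7-fold and 88.4-fold lower. Part of each bound came from BVSAF CD43+ cells, which had no read of these genes. With SB/CHIR, HOXA9 stood at 3.82 against 81.9 CPM, HOXA10 at 1.05 against 35.9 CPM and HOXA11 at 0.552 against 45.3 CPM. The bounds do not apply to SB/CHIR alone. SELE was at least 118-fold and NOTCH4 at least 61.1-fold lower, while HOXB9 was lower by only 1.58 ± 0.23 on the log2 scale. All 16 erythroid genes, 10 megakaryocyte genes, 13 pan-hematopoietic genes and 14 proliferation genes were higher. Camera called the erythroid list (adjusted p = 7.5e-07, or 0.30 with an estimated correlation) and the proliferation list (1.8e-08, or 0.19). All 19 arterial and Notch genes were lower (camera adjusted p = 8.8e-10, kept at 0.0086 with an estimated correlation), as were all 17 pan-endothelial (8.6e-10, or 0.12) and all 11 HOXA genes (0.00029, or 0.29). In total 6500 genes were higher and 7174 lower, 13674 together, against 7130 in EN_30_d11P alone and 7222 in EN_39_d10 alone.

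Against the same mCherry+ CD34+ cells, the mCherry+ CD34- cells (4 libraries) were higher in epithelial, endoderm and mesenchymal genes, though the endoderm list was not called with an estimated correlation. PCDH20, a protocadherin, was higher by 6.76 ± 0.46 (adjusted p = 1.4e-10) and TFCP2L1, a factor of naive pluripotency and kidney epithelium, by 6.38 ± 0.37 (adjusted p = 1.8e-11), at 48.7 against 0.624 CPM. VENTX, a homeobox gene of early embryos, was higher by 6.21 ± 0.44 and the cofactor VGLL3 by 6.09 ± 0.36. NANOG was higher by 5.52 ± 0.39 (adjusted p = 7.8e-10), at 17.0 ± 1.94 CPM with BVSAF and 6.25 ± 2.84 CPM with SB/CHIR (2 libraries each). CDH1 was higher by 5.27 ± 0.35, EPCAM by 2.66 ± 0.24 (adjusted p = 6.7e-09), the keratin gene KRT18 by 2.78 ± 0.22 and COL1A1 by 4.93 ± 0.32. The kidney and heart homeobox gene IRX1 was at least 22.2-fold higher. Endothelial genes were lower, among them CLDN5 (-9.40 ± 0.34, adjusted p = 2e-14), CDH5 (-7.12 ± 0.35), the adhesion receptor GPR116 (-9.19 ± 0.35) and the lymphoid GTPase GIMAP4 (-9.14 ± 0.28, adjusted p = 4.6e-15). SOX17 itself was lower by 1.89 ± 0.26 on the log2 scale (adjusted p = 2.6e-06). CARTPT and FCGR2B were at least 163-fold and 111-fold lower. All 11 endoderm genes were higher (camera adjusted p = 0.00039, or 0.092 with an estimated correlation), as were all 8 epithelial genes and 9 of 11 cardiac genes (camera adjusted p = 0.00043, or 0.05, and 0.036 with reversed columns). Pan-endothelial genes were lower in 17 of 17 cases, arterial genes in 15 of 19 and hematopoietic transcription factors in 11 of 16, and mesenchymal genes were higher in 16 of 17. These last lists and the epithelial list were called by camera (adjusted p from 2.1e-14 to 0.00026), with an estimated correlation too (adjusted p = 0.021 for each). In total 6184 genes were higher and 5944 lower, 12128 together, and the count was 7807 without EN_39_d10, 7684 without EN_39_d10P and 7869 in EN_39_d10 alone.

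Marker-negative cells (6 libraries) differed from mCherry+ CD34+ cells (6 libraries) by mesenchymal, cardiac and epithelial genes. The mesenchymal list stayed called with an estimated correlation, and the cardiac and epithelial lists did so only with the design columns in reverse order (adjusted p = 0.031 and 0.045). The synaptotagmin SYT10 was higher by 6.73 ± 0.37 (adjusted p = 3.8e-12), the growth factor protease PAPPA2 by 5.59 ± 0.23 (adjusted p = 6.3e-14, 127 against 2.65 CPM), the matrix gene MXRA5 by 5.58 ± 0.33 and RELN by 5.69 ± 0.43. COL1A1 was higher by 5.10 ± 0.30 (adjusted p = 1.1e-11), COL3A1 by 3.98 ± 0.24, DCN by 3.81 ± 0.24, cardiac troponin TNNT2 by 4.83 ± 0.28 and smooth muscle actin ACTA2 by 2.46 ± 0.18. The ovarian and amniotic mucin MUC16 was higher by 5.76 ± 0.42 and EPCAM by 2.28 ± 0.22. GIMAP4 (-9.98 ± 0.25, adjusted p = 8.2e-17), GPR116 (-9.94 ± 0.30) and CLDN5 (-9.71 ± 0.28, adjusted p = 4.5e-16) were lower. Against the same reference libraries, epithelial and mesenchymal genes had medians of 4.25 and 3.62 here and 3.89 and 3.43 in mCherry+ CD34- cells, and endoderm genes -0.86 and 3.73. The CD34- populations were not compared directly with each other. Mesenchymal genes were higher in 16 of 17 cases (camera adjusted p = 1.8e-10, kept at 0.045 with an estimated correlation), epithelial genes in 8 of 8 (1.5e-06, or 0.056), cardiac genes in 10 of 11 (0.00021, or 0.056) and trophoblast and amnion genes in 6 of 6 (0.00041, or 0.083). Pan-endothelial genes were lower in 17 of 17 cases (4.4e-14, kept at 0.044). In total 6360 genes were higher and 6348 lower, 12708 together, against 4691, 7743 and 7866 in EN_30_d11P, EN_39_d10 and EN_39_d10P alone.

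The lists not yet described gave these results for the mean treatment. CDX genes and HOX cofactors rose in 2 and fell in 1 of 9 cases (camera adjusted p = 0.72), venous and lymphatic genes fell in 2 of 10 (0.59) and arterial and Notch genes rose in 3 and fell in 3 of 19 (0.91). Hematopoietic transcription factors rose in 2 and fell in 6 of 16 (0.23), stem cell surface and niche genes rose in 1 and fell in 1 of 10 (0.77) and pan-hematopoietic genes rose in 1 and fell in 3 of 13 (0.13). Myeloid and mast cell genes rose in 1 and fell in 4 of 17 (0.048, or 0.55 with an estimated correlation), with a median of -0.74 that was -0.40 at the floor. Paraxial and intermediate mesoderm genes rose in 2 and fell in 1 of 12 (0.98), endoderm genes rose in 1 and fell in 4 of 11 (0.074), trophoblast and amnion genes rose in 2 of 6 (0.05) and neural genes rose in 2 and fell in 1 of 5 (0.23). BMP targets rose in 3 and fell in 1 of 11 (0.98), activin and TGF-beta targets fell in 2 of 7 (0.55) and retinoid pathway genes rose in 3 and fell in 1 of 9 (0.49). Fetal RNA-binding and growth genes rose in 1 and fell in 3 of 8 (0.33), stress and immediate early genes rose in 2 and fell in 5 of 10 (0.065), and hypoxia and glycolysis genes rose in 3 and fell in 1 of 11 (0.63). Median and mean log2 change differed in sign for CDX genes and HOX cofactors (-0.19 and 0.39), venous and lymphatic genes (0.02 and -0.10), stem cell surface and niche genes (0.06 and -0.11), paraxial and intermediate mesoderm (-0.05 and 0.12), BMP targets (-0.07 and 0.01), activin and TGF-beta targets (-0.02 and 0.06) and the retinoid pathway (-0.02 and 0.37), and camera took the sign of the mean for each of them but CDX and activin.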

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

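Of the tests in this part, those for carried-over cells and for depth were chosen only after the results were seen, and the regroupings of libraries had been planned before.

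The fall of erythroid and megakaryocyte genes with SB/CHIR in mCherry+ CD34+ cells moved with the CD43 transcript in the BVSAF libraries. If CD43+ cells had been carried over, all blood genes of a BVSAF library should reach a similar share of their CD43+ level. The median share of the erythroid genes was 5.67%, 1.36% and 0.237% in EN_30_d11P, EN_39_d10 and EN_39_d10P, and megakaryocyte genes reached 8.61%, 1.96% and 0.633%. Other blood genes reached 1.79, 1.37 and 1.81 times the erythroid share in EN_30_d11P, EN_39_d10 and EN_39_d10P. Carried-over CD43+ cells in the BVSAF libraries may therefore account for the fall, though the shares were not equal. That test rested on 3, 2 and 2 genes in these sets, kept because SB/CHIR mCherry+ CD34+ cells held at most 1% of their CD43+ level. In the SB/CHIR libraries the erythroid share was 0.0414%, 0.0395% and 0.0523%, and an early blood program within the sorted cells was not separated from carry-over. Carry-over of CD43+ cells into the other CD43- populations, which enter the mean treatment comparison, was not tested.

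HOXA9, HOXA10 and HOXA11 had no read in BVSAF CD43+ cells and were detected in SB/CHIR CD43+ cells. For HOXA9, carried-over mCherry+ CD34+ cells would have needed a share of 5.21% and 4.79% in the libraries, while EMCN stood at 0.31% and 0.287%, ROBO4 at 0.116% and 0.196% and CLDN5 at 0.102% and 0.647%. Carried-over mCherry- CD34+ cells would have needed 12.1% and 18.2%, while EMCN stood at 1.04% and 1.15% and KDR at 2.61% and 3.45% of their level. In each library at least 3 pan-endothelial genes for the former source and 4 for the latter were under 0.25 of the share needed for HOXA9, which makes carry-over from either unlikely. For HOXA10 these were 2 and 1 genes and for HOXA11 0 and 0, where the test could not tell. Lower depth of the BVSAF CD43+ libraries does not account for HOXA9, since their highest floor was 0.179 CPM and HOXA9 stood at 3.82 CPM with SB/CHIR. For HOXA10 and HOXA11 the floor could not tell, as they were at only 0.688 and 0.25 CPM in the SB/CHIR library of EN_39_d10P. The BVSAF CD43+ libraries held 20.86, 19.58 and 20.01 M counts, and the SB/CHIR CD43+ libraries held 18.91 and 18.08 M. These totals argue against lower depth of the BVSAF libraries for both genes, though counting error at such low levels stays open. Antisense or read-through transcripts of the cluster stay open, since the strand of counting was not stated.

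Endoderm genes fell with SB/CHIR in mCherry+ CD34+ cells as they did in mCherry+ CD34- cells, which share the reporter gate. The endoderm genes of the BVSAF libraries reached a median of 6.98% of their mCherry+ CD34- level in EN_39_d10 and 4.99% in EN_39_d10P, and mesenchymal genes reached 8.24% and 12.4%. The higher ratio of endoderm to mesenchyme share was 0.847, so carried-over CH+34-43- cells in the BVSAF libraries may account for these genes. The test could not decide this, because mesenchymal transcripts made by mCherry+ CD34+ cells themselves would also give a low ratio. COL3A1 stood at 1140 CPM in BVSAF and 813 CPM in SB/CHIR mCherry+ CD34+ cells, against 16100 and 13400 CPM in mCherry+ CD34- cells. EN_30_d11P held no mCherry+ CD34- library and could not be tested.

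Whether groups drawn at random would call as many genes was tested by regrouping libraries. With treatment labels swapped within population and set, 1 of 60 splits, the real one, reached 4201 genes and the highest other called 297. These swaps were made separately for each population, so they could not test a difference between cultures shared by the populations of a set. Swaps of whole title sets were not run, and 3 sets allow too few of them for a share under 0.05. The other regroupings were fitted on the compared libraries alone, so their real counts differ from those of the fit on all libraries. For CD43+ against mCherry+ CD34+ cells 1 of 50 splits, the real one, reached 12552 genes and the highest other 137. For mCherry+ CD34- cells 1 of 49 reached 11622 with a highest other of 0, and for marker-negative cells 1 of 50 reached 11470 with a highest other of 0. For mCherry+ CD34+ against mCherry- CD34+ cells 1 of 50 reached 5733, and the highest other, 4323, relabelled nearly all libraries. For the treatment in mCherry+ CD34+ cells (real 1188, highest other 0) and in marker-negative cells (real 2325, highest other 0), the 10 splits are too few for a share under 0.05.

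The following values stood out because the treatment response differed between populations. The interaction held 1396 genes, the response of CD43+ minus mCherry+ CD34+ cells 484 genes and that of mCherry- CD34+ minus mCherry+ CD34+ cells 72 genes. For CD43+ minus mCherry+ CD34+ cells the differences at the floor were 2.81 for HOXA9 and 1.26 for HOXA10. In that comparison GRIP2 differed by 5.82, ASGR2 by 5.42, GYPB by 5.23, HOXB8 by 3.18, HOXB9 by 2.09 and HOXB7 by 1.45. Lower there were DLK1 (-2.58), SEMA3C (-2.57), CRYM (-2.31), ROBO2 (-1.87) and INSR (-1.73). The difference of GYPB came from its fall in mCherry+ CD34+ cells (-5.59), so the doubt about carried-over CD43+ cells applies to it and to other blood genes higher in that comparison. Of the genes given for it, only HOXA9, HOXB8 and SEMA3C kept their calls whichever library was left out. For mCherry- CD34+ minus mCherry+ CD34+ cells BEX1 differed by 2.60, RYR3 by 2.59, BHMT by 2.38 and DPEP3 by 2.12. Lower in that comparison were PRND (-6.38), BTNL9 (-4.41), IGF2 (-3.45), SLC4A4 (-3.45), FCGR2B (-3.34), DLK1 (-3.14), CXCR4 (-2.87), UNC5B (-1.56) and EFNB2 (-1.51). Of these genes only RYR3, PRND, BTNL9, IGF2 and SLC4A4 kept their calls whichever library was left out.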

How the results depend on the processing

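Except for the fit without the day 11 BVSAF libraries named in the processing text, no alternative here was chosen after the results were seen, and the cause of a difference was not tested. Counts of called genes are given where they moved by over 1.5 times from the main count. Without the block they were 464 for mCherry+ CD34+ (main 821), 439 for mCherry- CD34+ (955), 378 for mCherry+ CD34- (777), 539 for CD43+ (907), 1581 for marker-negative cells (2526), 694 for the interaction (1396), 242 for the CD43+ difference (484) and 18 for the CD34+ difference (72). DESeq2 gave 2423, 815 and 209 for the interaction, the CD43+ difference and the CD34+ difference, no filter 774 and 209 and limma voom 304 and 117 for these differences. Without EN_30_d11P the counts were 1653 for mCherry- CD34+, 1488 for mCherry+ CD34-, 98 for CD43+, 120 for the CD43+ difference and 192 for the CD34+ difference. Without EN_39_d10 they were 804 for the mean treatment (4201), 99, 59, 0, 252 and 342 for the populations in the order above, 18 for the interaction, 64 for the CD43+ difference, 3 for the CD34+ difference, 1508 for mCherry+ CD34+ against mCherry- CD34+ (5830) and 7807 for mCherry+ CD34- against mCherry+ CD34+ cells (12128). Without EN_39_d10P they were 1343, 207, 64, 101, 437, 814, 198, 84, 11, 1492 and 7684 in the same order. In EN_30_d11P alone they were 0 for the mean treatment, 0 for mCherry+ CD34+ against mCherry- CD34+, 7130 for CD43+ (13674) and 4691 for marker-negative cells against mCherry+ CD34+ (12708). In EN_39_d10 alone they were 740, 1378, 7222 and 7743 in that order, with 7869 for mCherry+ CD34-. In EN_39_d10P alone they were 746 for the mean treatment, 1067 for mCherry+ CD34+ against mCherry- CD34+ and 7866 for marker-negative cells. From the compared groups alone they were 1852 for mCherry- CD34+, 546 for CD43+ and 137 for the CD43+ difference. With any 1 library left out, the lowest and highest counts were 3204 and 4749 for the mean treatment, 375 and 747 for mCherry+ CD34+, 175 and 902 for mCherry- CD34+, 89 and 428 for mCherry+ CD34-, 153 and 1313 for CD43+, and 1197 and 2185 for marker-negative cells. They were 899 and 1638 for the interaction, 106 and 630 for the CD43+ difference, 16 and 88 for the CD34+ difference, 3592 and 6492 for mCherry+ CD34+ against mCherry- CD34+, 12707 and 13490 for CD43+, 10862 and 11937 for mCherry+ CD34- and 11904 and 12549 for marker-negative cells against mCherry+ CD34+. Without both day 11 BVSAF libraries the mean count was 3593 and the mCherry+ CD34+ count 553. The share of called genes that were higher was 47.7% without EN_30_d11P against 58.5% for the mean treatment, and 77.2% with limma voom against 90.4% in CD43+ cells. Of 165 list calls by camera 16 held with an estimated correlation, while camera without the block made 149 calls and fry 162, not all for the same lists. The median log2 change of all genes for CD43+ against mCherry+ CD34+ cells was -0.128 in DESeq2, -0.129 with RLE and -0.109 without the block (main -0.095).

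Gene values turned direction in these cases, 31 of 1572 named gene results. For the mean treatment in EN_30_d11P alone, EMCN was -0.02, HES1 0.09, HAND1 0.56, ID1 0.05, PMEPA1 0, H19 0.31, FOS 0.29 and FOSB 0.22. In EN_39_d10 alone HOXB8 was -0.04, MMRN2 -0.14, CNN1 0 and LHX1 -0.12, and in EN_39_d10P alone ISL1 was -0.38. In CD43+ cells ORM1 was -0.29 without SB/CHIR CD43+ replicate 1 and 5.30 without replicate 2. For mCherry+ CD34+ against mCherry- CD34+ in EN_30_d11P alone, STAB2 was 1.13, PROM1 0.39, MPO 0.76, SMAD7 0.21 and SKIL 0.29. For CD43+ against mCherry+ CD34+ PBX2 was 0.78, CDH1 0.02 and DLK1 -0.45 in EN_30_d11P alone, HOXB4 -0.17, HOXC10 1.15 and HNF4A -0.23 in EN_39_d10 alone, and EGFL7 0.22 and HES1 0.10 in EN_39_d10P alone. For mCherry+ CD34- against mCherry+ CD34+ HOXD12 was -0.14 without EN_39_d10. For marker-negative against mCherry+ CD34+ cells JAG1 was -0.01 and DUSP1 -0.16 in EN_30_d11P alone, and CD48 was 0.25 in EN_39_d10P alone. Of the named gene results 590 kept their call in every alternative that gave them a value, outside the left-out libraries. Fits on EN_30_d11P, EN_39_d10 and EN_39_d10P alone gave values for only 887, 1149 and 1145 of them. The fit on the compared groups alone was not run for the mean treatment and the interaction, and EN_30_d11P alone could not be run for mCherry+ CD34- cells.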

Other observations

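None of the tests in this part was chosen after its result was seen, as it restates values of the planned comparisons.

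IGF2 and DLK1, imprinted genes of fetal growth, moved in opposite directions between the populations. With SB/CHIR, DLK1 was at 398 ± 146 CPM against 151 ± 80.2 CPM in mCherry+ CD34+ cells (3 libraries each), a log2 change of 1.41 ± 0.36 (adjusted p = 0.029). That call was lost without EN_39_d10 (1.25), without EN_39_d10P (1.41) and without SB/CHIR replicate 1 (1.13) or 2 (1.39) or BVSAF replicate 2 (1.24) or 3 (1.14). In mCherry- CD34+ cells DLK1 changed by -1.73 ± 0.40 (adjusted p = 0.016), a call also lost without either BVSAF library (-1.75 and -1.71). The direct test between these populations gave -3.14 ± 0.55 (adjusted p = 0.011), a call lost without BVSAF mCherry+ CD34+ replicate 2 (-2.97) or either BVSAF mCherry- CD34+ library (-3.16 and -3.12), and without EN_39_d10 (-2.95) or EN_39_d10P (-3.22). HLF, a stem cell factor, was at 75.7 CPM in SB/CHIR mCherry+ CD34+ cells and 5.60 CPM in SB/CHIR mCherry- CD34+ cells.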
